A study of Mus musculus with 2 samples.

How the data were processed

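Per the labels' protocols, T cells positive for TCRb and CD4 were sorted from the stromal vascular fraction of visceral adipose tissue of 10 pooled mice and loaded on a droplet 3′ single-cell platform. It is unclear whether 10 mice went into each pool or into both together. The labels name different kit versions in the series design and in the sample protocol. The design text also mentions crosses with a CD70 transgene that are not among these samples. Per the file headers, the authors counted reads with Cell Ranger 6.1.1 against mm10, and the deposited matrices hold UMI counts of called cells for 32285 genes. Each matrix also holds 1 antibody feature, with 0 UMIs in both libraries. The aligner settings beyond this are not given in the sources used here. The sample groups, WT and CD27_KO, come from the titles, as the genotype entry is the same for both.

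Everything after the deposited counts was computed here with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Sequence matches used BLAST 2.17.0. Gene positions come from GENCODE vM21 (mm10, 1-based), which places 32235 of the genes and leaves 50 without a position.

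Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed 60 WT and 40 CD27_KO barcodes. Scrublet was run per library and marked no cell, with thresholds of 0.584 and 0.502. Counts were scaled to 10000 per cell and log-transformed, genes seen in at least 10 cells were kept, and 2000 variable genes were chosen without T cell receptor and immunoglobulin segments, ribosomal, mitochondrial, haemoglobin and sex-linked genes and Cd27. Values were limited to 10 after scaling. Both libraries were clustered jointly, without batch correction, by 30 principal components, 20 neighbours and Leiden at resolution 1 with seed 0.

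A cluster took the cell type with the highest median log2 ratio of its markers over all other cells, with a pseudocount of 10 CPM, if at least 3 markers were 1.5-fold enriched and seen in at least 5% of its cells. It stayed unnamed if the next type with at least 3 enriched markers was a lymphocyte type, innate type 2 cells included, and reached 0.5 of that median. The markers were fixed before the data were examined and this rule was set afterwards. Clusters of dendritic, B cell or macrophage, and stromal character, 136 WT and 65 CD27_KO cells, were left out of all T cell results.

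Shares of cells carry exact Clopper-Pearson intervals and summed UMIs carry exact Poisson intervals, and ratios carry the matching exact intervals, all at 95%. No p-value, standard error or test across samples was computed, as there is 1 library per group. CPM and log2 ratios of CD27_KO over WT were computed from UMIs summed over cells. Ratios with 0 counts on one side were set against a floor of 3 counts. A gene was counted as apart at 1.5-fold with at least 100 UMIs over both libraries, over all T cells and in each named class with at least 200 cells in each library. The number of genes that counting error alone would place there was computed for each comparison, with each UMI taken as independent. For shares of cells with a UMI, each cell was thinned to 1300 UMIs, and cells below this depth were left out.

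The genes named were fixed by rule. They include Cd27, Cd70, Cd4, Foxp3, Gata3, Il5, Il13, Il1rl1, Pparg, Klrg1, Tbx21, Ifng and Il17a, the 12 furthest in each direction over all T cells, up to 6 furthest in each direction in a class, and up to 4 furthest members of each list. Receptor segments, ribosomal, mitochondrial and sex-linked genes and unnamed models were given as groups. Leading genes of clusters were taken from the 10 highest of each cluster. Genes near Cd27 and genes apart in every class were chosen after their values were seen.

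The 21 gene lists were fixed beforehand: VAT Treg signature, type 2 cytokines, IL-33, IL-25, TSLP and IL-2 receptors, type 1 effector, type 17 effector, TNF receptor superfamily and ligands, TRAF and NF-kB signalling, costimulation and inhibition, survival and apoptosis, tissue residency, recirculation, T cell receptor signalling and early activation, dissociation and immediate early genes, interferon response, cell cycle, glycolysis, nuclear oxidative phosphorylation, fatty acid uptake and oxidation, chemokine receptors, sex-linked genes and genes of chromosome 6 near Cd27. Members needed at least 20 UMIs over both libraries and a list at least 3 measured members. Each median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression.

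The steps were tested on simulated data drawn as Poisson counts with no spread between mice, so they show what counting error does and no more. Over all T cells, 94 of 100 genes set 2-fold apart and 96 of 100 set 4-fold apart were found, and 23 of 9562 genes with no difference passed 1.5-fold. In Th2-like cells these were 86, 70 and 122 of 3972, in Treg-like cells 89, 89 and 58 of 3019, in naive-like cells 91, 91 and 92 of 2832, and in Th1-like cells 91, 88 and 39 of 7523. A simulated gene left with under 100 UMIs counted as missed, and the UMIs of the missed genes were not recorded. Intervals held the true ratio in 95.9% of 1000 draws over all T cells. Of the 21 lists with no difference, 3 lay outside the middle 95% of random lists over all T cells, and a doubled list lay at percentile 100.

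The alternatives fixed beforehand were a strict filter (at least 1000 genes, at most 5% mitochondrial UMIs), every deposited barcode, doublets kept, resolutions 0.6 and 1.5, variable genes without the Th2 and type 2 genes, WT cells clustered alone with classes passed to CD27_KO cells, clustering of thinned cells, median-of-ratios scaling, the mean of per-cell fractions, limits of 30 and 300 UMIs, classes given the same share in both libraries, list members with at least 100 UMIs, unthinned shares and shares at 2600 UMIs. Added after the results were seen were removal of top-scored doublets (0.8% per 1000 cells) and cells above 2 times the median UMIs, shares without clusters 3 and 6, shares outside the naive-like class and outside it and cluster 4, and variable genes without the Treg genes. Near-identical copies were sought as matches of at least 95% identity over 100 bases in the last 500 bases of a transcript. Raw reads were not analysed here.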

Results

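CD4 T cells of mouse visceral adipose tissue (VAT, the fat around the abdominal organs) were profiled by droplet single-cell RNA sequencing in 2 libraries, 1 from wild-type mice (WT) and 1 from mice lacking CD27 (CD27_KO). CD27 is a costimulatory receptor of the TNF receptor family on T cells, and CD70 is its ligand. Cells positive for TCRb and CD4 were sorted from the stromal vascular fraction, the cells left after adipocytes are removed, of pooled mice (10, per the labels' protocols). The WT library held 6398 barcodes with 16628623 unique molecular identifiers (UMIs), and the CD27_KO library held 6893 barcodes with 20191704. After filtering, 6338 WT and 6853 CD27_KO cells remained, with medians of 1945.5 and 2209 UMIs and of 834 and 1004 genes per cell. T cells made up 6202 of the WT and 6788 of the CD27_KO cells, with 15824202 and 19784355 UMIs. With 1 library of pooled mice per group, no difference could be set against a spread between mice or libraries. Intervals (95%, exact) cover counting error only, and no test across samples was possible. For summed UMIs they take each UMI as independent, so they are too narrow for genes whose UMIs lie together in few cells. The labels give the same genotype entry for both libraries, so the groups rest on the library titles and on the Cd27 counts.

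The targeted gene, Cd27 (ENSMUSG00000030336; chromosome 6, 125232622 to 125237010, mm10), was nearly absent from the CD27_KO library. Its transcript gave 2072 UMIs in WT T cells, or 131 CPM (UMIs scaled to the same library total), and 15 UMIs in CD27_KO T cells, or 0.758 CPM. The log2 ratio of CD27_KO over WT was −7.43 (interval −8.27 to −6.71). The few CD27_KO molecules lay in 14 cells, against 1578 cells in WT. Which part of the gene the mutation removes is not given in the sources used here. The ligand gene Cd70 was near the floor in both libraries, with 8 and 4 UMIs.

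The first comparison asked how the make-up of the VAT CD4 T cell pool differed without CD27, the subject of the study. The Th2-like class, with 9 of 13 Th2 markers enriched and Calca, Csf2, Tnfsf11 and Il4 among its leading genes, took a larger share of the CD27_KO library. Its second type was innate type 2 cells, of which Calca is a marker. That type had 3 enriched markers and a median log2 ratio of 0.655, against 1.58 for Th2. Regulatory (Treg-like) and naive-like cells took smaller shares there. Th2-like cells were 4.68% of WT T cells (interval 4.16 to 5.23) and 15.9% of CD27_KO T cells (15.0 to 16.8), a ratio of 3.40 (2.98 to 3.88). Treg-like cells, led by Cxcl2, Ikzf2, Foxp3 and Ctla4, made up 12.4% of WT (11.5 to 13.2) and 4.70% of CD27_KO T cells (4.21 to 5.23), a ratio of 0.381 (0.333 to 0.434). Naive-like cells, with Ccr7 and Lef1, made up 20.5% (19.5 to 21.6) and 4.52% (4.04 to 5.04), a ratio of 0.220 (0.194 to 0.2496). The markers were fixed before the data were examined, but the rule that turns them into cluster names was set afterwards. Each of these 3 directions held under every alternative clustering that gave the class. The naive-like ratio lay near the low end of its alternatives, which reached 0.395. The Treg-like ratio was the highest of its alternatives, the lowest being 0.145 (0.1145 to 0.182) with WT cells clustered alone. The shares also depended on the settings: the WT Treg-like share ran from 8.82% to 22.1%, and was 46.1% under a strict cell filter that kept 2033 WT T cells.

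**Figure D1:**
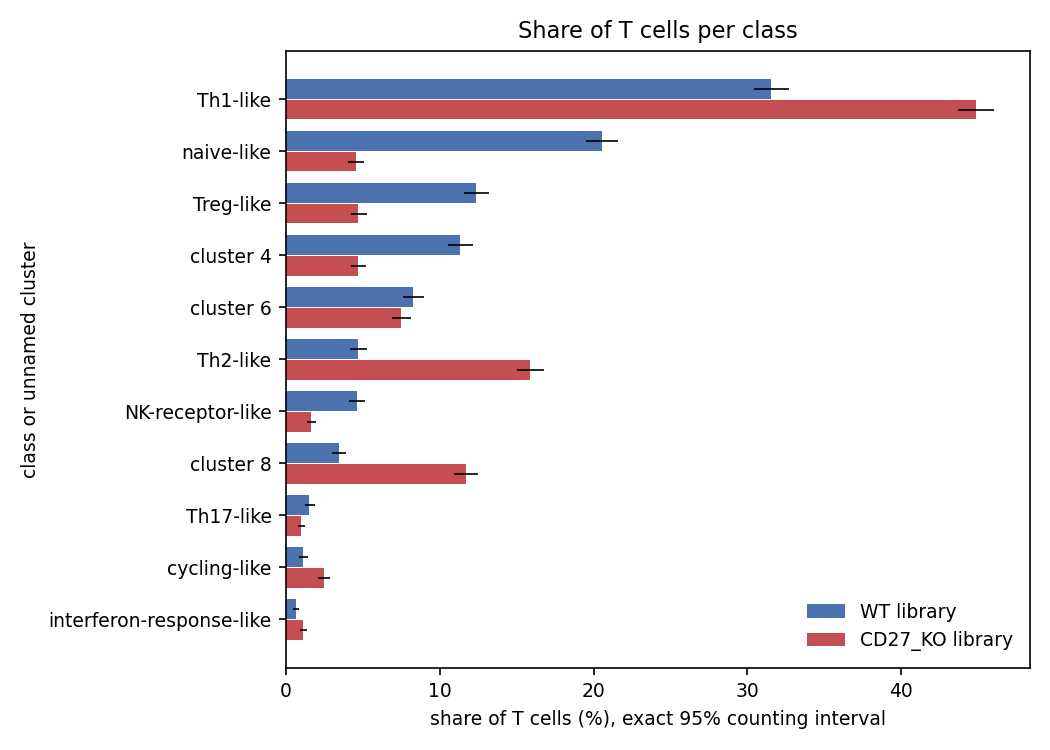
Share of T cells in each named class or unnamed cluster (x axis, percent) in the WT and CD27_KO libraries, 1 library per group; bars give the share and lines its exact 95% counting interval. Th2-like cells take 4.68% of WT and 15.9% of CD27_KO T cells, while naive-like cells take 20.5% and 4.52%.

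At these settings the Th1-like class was the largest in both libraries, at 31.6% of WT and 44.9% of CD27_KO T cells (ratio 1.42, interval 1.34 to 1.51). It joined 4 clusters that did not go the same way. Cluster 0, led by Ly6c2, Ccl5 and Nkg7, was 17.9% in WT and 9.61% in CD27_KO, whereas cluster 10, led by P2rx7, Lyst and Mmp9, was 5.84% and 27.2%. Cluster 3 (6.95% and 6.73%) and cluster 11, with Gzma and Cx3cr1 (0.838% and 1.38%), made up the rest. Cluster 10 took the Th1 name on 3 enriched markers, none among its 10 leading genes, and the ratio of the whole class fell below 1 under 3 alternatives. Cycling-like cells (Mki67, Top2a) were 1.11% of WT and 2.45% of CD27_KO T cells, and interferon-response-like cells (Ifit1, Isg15) 0.629% and 1.10%. NK-receptor-like cells (Klrk1, Klrd1, Fcer1g) were 4.60% and 1.64%, and Th17-like cells (Tmem176a, Ccr6) 1.52% and 0.972%. Unnamed cluster 4, with naive and follicular helper markers, was 11.3% and 4.68%. Unnamed cluster 6, which mixed Treg and Th2 markers and had many UMIs per cell, was 8.26% and 7.47%. Unnamed cluster 8, led by Bcl2a1d, Bcl2a1b, Bhlhe40 and Il4, was 3.42% and 11.7%.

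Single genes were also followed by the share of cells with at least 1 UMI, after each cell was thinned to 1300 UMIs; this left out 536 WT and 54 CD27_KO cells. Cells with Il4, the cytokine that drives Th2 differentiation, were 1.09% of WT and 6.01% of CD27_KO T cells (2.03% and 10.4% before thinning). The shares with Il5, a growth factor of eosinophils, were 0.812% and 0.876% (1.29% and 2.09%), and those with Il13 0.406% and 0.535% (0.532% and 1.03%), within counting error of each other after thinning. The share with Gata3, the Th2 master regulator, was 19.9% in WT and 29.6% in CD27_KO (29.6% and 44.2%), and with Il1rl1 14.8% and 20.03% (21.4% and 27.9%). Foxp3, the Treg master regulator, was seen in 4.69% and 2.27% (9.80% and 4.67%). The shares with Areg, which encodes the repair factor amphiregulin, were 12.8% and 6.04% (15.8% and 8.54%). For Klrg1, which marks differentiated effector and tissue Treg cells, they were 11.1% and 8.97% (17.6% and 16.8%). For Ifng, the Th1 cytokine, they were 6.78% and 9.95% (11.3% and 16.5%), and for Pparg, a nuclear receptor used by VAT Treg cells, 1.62% and 2.36% (3.02% and 5.57%). For Il17a they were 0.159% and 0.0891% (0.210% and 0.147%), for Cd70 0.0706% and 0.0149% (0.113% and 0.0589%), and for Cd27 15.1% and 0.0891% (25.4% and 0.206%).

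Naive-like cells, which should lack most of these transcripts, served as a background, and whether it comes from free RNA was not tested. Over 1212 WT and 306 CD27_KO naive-like cells, with median depths of 1870 and 2088 UMIs before thinning, Il4 was seen in 0.0825% and 0.327%, Ifng in the same shares, Foxp3 in 0.413% and 0.654%, and Il1rl1 in 0.0825% and 0.654%. Gata3, which naive T cells also transcribe, was seen in 4.95% and 4.58%. Il5, Il13 and Pparg were in no naive-like cell of either library, for which the upper limits of the exact intervals are 0.304% and 1.198%. Areg was in 0.495% and Klrg1 in 0.248% of WT naive-like cells, and neither was seen in CD27_KO ones. The library-wide shares of Il4, Foxp3, Gata3, Il1rl1, Areg, Klrg1 and Ifng lay above these values in both libraries. Those of Il5 and Il13 in CD27_KO lay below the limit of 1.198% that its few naive-like cells allow.

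The next comparison covered every gene, with UMIs summed over all T cells. The cytokine gene Il4 was among the genes furthest higher in CD27_KO, and Il10, which encodes an anti-inflammatory cytokine, was among the furthest lower. Of 9754 genes with at least 100 UMIs, 685 were at least 1.5-fold higher in CD27_KO and 279 at least 1.5-fold lower. The counting error alone would put 13.7 and 11.4 genes there. This takes each UMI as independent, but UMIs of some genes lie together in few cells, as with 188 WT Cxcl2 UMIs in 1 cell. The expected counts, here and within classes, may therefore be too low. The median gene was 0.17 higher in CD27_KO on the log2 scale, and relative to that shift the split was 324 higher and 416 lower, so the excess of higher genes depends on the scaling. Ribosomal protein genes took 32.2% of WT and 27.6% of CD27_KO UMIs, and mitochondrial genes 2.47% and 2.85%. T cell receptor segments (ratio 1.03), immunoglobulin segments (0.805) and unnamed gene models (1.01) are given as groups.

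Among the 12 genes furthest higher, Il4 went from 175 UMIs in WT to 1088 in CD27_KO, 4.97-fold (interval 4.24 to 5.87). With each class given the same share in both libraries its log2 ratio of 2.31 was 1.33, and those of St5 (2.35) and Vmn2r100 (2.15) were 1.20 and 1.02, so part of these differences goes with the class shares. Samd11, a nuclear protein gene on chromosome 4, had 55 and 1171 UMIs, 17.03-fold (13.0 to 22.7), and Mxra8, the gene of an alphavirus receptor, 8 and 151 UMIs, 15.1-fold (7.47 to 35.6). Tnfrsf14, another TNF receptor family member, was 8.24-fold higher on 10 and 103 UMIs. These 3 genes lie within the last part of chromosome 4, with starts at 156246966, 155839680 and 154921933. The aldose reductase-related gene Akr1b7 had no UMI in WT and 365 in CD27_KO. Against a floor of 3 counts over the library this was 97.3-fold higher, with a lower limit of 78.7. However, these UMIs lay in 9 cells, 162 of them in 1 cell. Rap1gap, Adamts13, Dach2, St5, Tmem181a, Plce1 and Vmn2r100 were between 4.44-fold and 7.47-fold higher. Stretches near-identical to the transcript ends of Samd11 (in 3 other genes), Tnfrsf14 (50), Adamts13 (4) and Tmem181a (2) exist elsewhere, so the origin of their reads is uncertain.

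Below Cd27, the 12 genes furthest lower in CD27_KO held 3 neighbouring neutrophil chemokine genes of chromosome 5. Cxcl2 had 13853 WT and 3018 CD27_KO UMIs, 5.74-fold lower (5.52 to 5.97), Cxcl3 was 6.09-fold lower on 268 and 55 UMIs, and Cxcl1 86.9-fold lower (23.6 to 725) on 139 and 2 UMIs. Cxcl2 has a near-identical stretch in Cxcl3, so reads of this pair are of uncertain origin. The WT Cxcl1 molecules came from 29 cells. Il10 had 416 and 88 UMIs, 5.91-fold lower (4.69 to 7.53). The zinc finger gene Zfp971 had 107 WT UMIs and none in CD27_KO, 44.6-fold lower against a floor of 3 counts (lower limit 35.6). However, 9 genes hold near-identical stretches, so the reads of Zfp971 too are of uncertain origin. Rln3, which encodes relaxin-3, was 9.87-fold lower on 363 and 46 UMIs, and Nrn1, which encodes neuritin, 7.71-fold lower on 333 and 54. Tmem108, Frmd5, Ctsh and Klrb1c, the gene of the NK1.1 antigen, were between 5.24-fold and 5.88-fold lower. For Tmem108 the log2 ratio of −2.55 was −0.71 with each class given the same share in both libraries, and −0.18 (−0.87 to 0.46) within naive-like cells, which hold most of it.

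The lineage genes followed the class shares in part. Foxp3 had a log2 ratio of −1.05 (−1.21 to −0.90; −0.31 with the class shares made the same), Gata3 of 0.62 (0.56 to 0.67), Il1rl1 of 0.44 (0.39 to 0.50), Pparg of 0.75 (0.52 to 0.97) and Klrg1 of −0.50 (−0.58 to −0.41). With the class shares made the same, Gata3 was at 0.29, Il1rl1 at 0.10 and Pparg at 0.28. Il5 was higher by 0.56 (0.31 to 0.82), and Il13 by 0.19 (−0.10 to 0.49), which counting error spans; with each class given the same share in both libraries both were lower, at −0.44 and −0.80. Ifng was at 0.75 (0.64 to 0.85) and its regulator Tbx21 at 0.36 (0.16 to 0.55), against 0.39 and 0.11 with the class shares made the same. The Th17 cytokine gene Il17a (0.43, −0.22 to 1.11) was too sparse to place. Cd4 was at 0.15, less than the shift of the median gene.

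Gene lists fixed before the data were examined were then compared by their median log2 ratio and its percentile among 10000 random lists matched on expression, which describes these 2 libraries and tests nothing. Cell cycle genes were higher in CD27_KO (median 0.73, percentile 100; 12 of 18 at least 1.5-fold higher, led by Ube2c, Top2a, Mki67 and Pclaf). Interferon response genes were also higher (0.44, percentile 99.96; Usp18, Rsad2 and Ly6a among the furthest), as were tissue residency genes (0.32, percentile 99.6; Bhlhe40 at 0.97 and the chemokine receptor gene Cxcr6 at 0.93). Of these genes, Usp18 lies 3.99 Mb from Cd27 on chromosome 6. Recirculation genes were lower (−0.38, percentile 0), with the lymph node homing gene Ccr7 at −1.77. The VAT Treg signature was lower (−0.50, percentile 0; Il10 −2.56, Ccr1 −1.99, Gzmb −1.83), although Pparg, Gata3 and Il1rl1 in it were higher. The costimulation and inhibition list (−0.23, percentile 0) was led by lower Tox, Pdcd1, Cd200 and Ctla4, but its median was 0.06 with each class given the same share in both libraries. The TNF receptor superfamily list (−0.15, percentile 0) held members on both sides: Tnfrsf9 at −1.73 and Tnfrsf4, the gene of OX40, at −0.96, but Tnfsf11, the gene of RANKL, at 1.36.

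With the classes held at equal shares in this way, the type 2 cytokine median was −0.80, against 0.19 over all T cells as they fell (percentile 61.0), where Il10 and Areg were lower and Il4 and Il6 higher. Both medians are the value of Il13, the middle of 7 measured members, and 69.9% of its WT UMIs came from 5 cells. At equal shares 4 of the 7 were at least 1.5-fold lower, but Il4 (1.33) and Il6 (1.12) stayed higher. Residency (0.13), recirculation (−0.05) and cell cycle (0.24) then lay within the middle 95% of random lists. The interferon median remained outside it, at 0.32, and so did the VAT Treg signature, at −0.35. Type 1 effector genes (−0.08, percentile 0.64), T cell receptor signalling (−0.13, 0.02) and dissociation genes (−0.17, 0.06) then lay below the random range, which they did not without this weighting. Without the weighting, most other medians over all T cells lay inside the random range. They were 0.30 for the IL-33, IL-25, TSLP and IL-2 receptors (percentile 97.0), 0.28 for TRAF and NF-kB signalling (96.9), 0.12 for type 1 effector genes (33.5), −0.10 for type 17 effector genes (8.08), 0.15 for survival and apoptosis (45.9), 0.07 for T cell receptor signalling (11.9) and 0.01 for dissociation and immediate early genes (10.6). Glycolysis (0.12, 34.7), oxidative phosphorylation (0.02, 13.7), fatty acid genes (0.14, 29.9) and chemokine receptors (0.15, 51.5) did not stand apart either. The sex-linked list was at 0.01 (10.6). The list of genes near Cd27 was at 0.05, low among random lists (1.74) but above 0 only under this scaling.

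**Figure D2:**
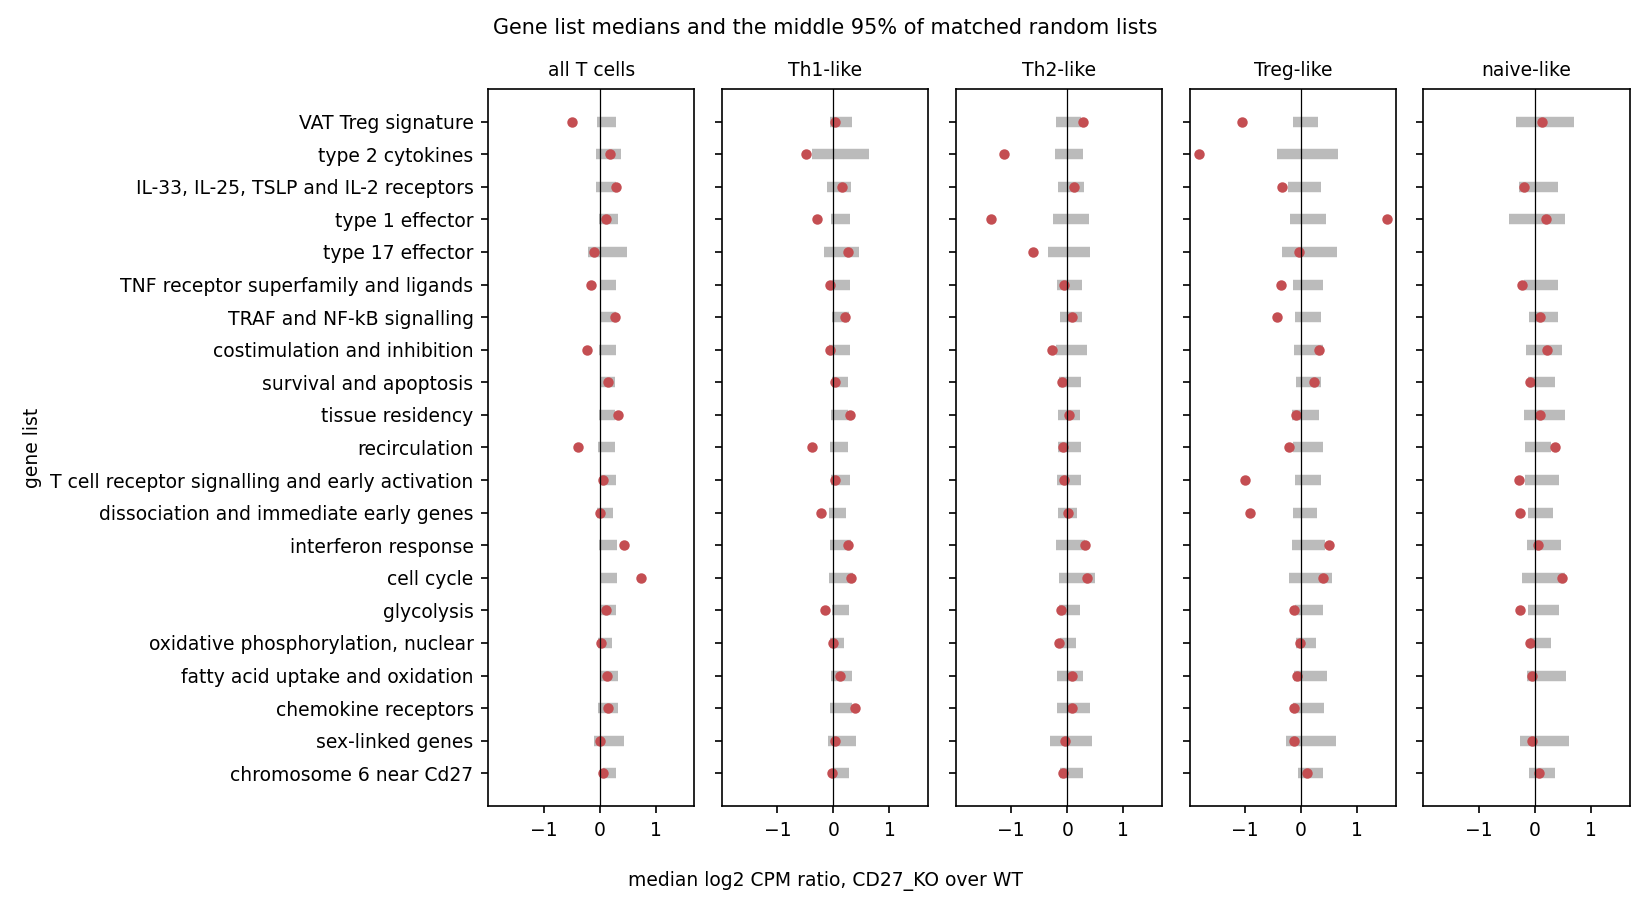
Median log2 CPM ratio of CD27_KO over WT for each gene list (points, x axis) over all T cells and within 4 classes, with the middle 95% of 10000 expression-matched random lists (grey bars); lists with under 3 measured members in a class have no point. The VAT Treg signature lies at −0.50 over all T cells and at −1.06 in Treg-like cells, and type 2 cytokines at −1.13 in Th2-like cells.

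Within Treg-like cells (766 WT and 319 CD27_KO), the question was whether the remaining Treg cells kept their VAT character. Their Foxp3 level was not lower in CD27_KO (log2 0.31, 0.08 to 0.55), but in this class the VAT Treg signature was. Of 12 measured members of the VAT Treg signature, 10 were at least 1.5-fold lower and none higher (median −1.06, percentile 0). Areg was at −1.89 (−2.03 to −1.75), Il10 at −1.82 (−2.40 to −1.29), Ccr1 at −1.82 (−2.67 to −1.05) and Il1rl1 at −1.70 (−1.93 to −1.49). Pparg (−1.20), Klrg1 (−0.95) and Gata3 (−0.77) went the same way. After thinning, Il1rl1 was seen in 48.8% of WT and 19.8% of CD27_KO Treg-like cells (61.0% and 23.2% before), Areg in 49.8% and 22.4% (55.0% and 27.6%), Klrg1 in 49.2% and 29.9% (58.9% and 42.6%) and Foxp3 in 24.6% and 29.5% (34.6% and 46.1%). Over all T cells with a Foxp3 UMI, in whichever cluster, the signature was lower by less, with a median of −0.37 (percentile 0) and 4 of 12 members at least 1.5-fold lower (Areg, Il10, Gzmb and Ccr1). None of 9 measured receptor genes of the IL-33 and IL-2 list, Il1rl1 among them, was 1.5-fold apart over those cells. In unnamed cluster 6, which also holds Foxp3, Il1rl1 (0.20), Gata3 (0.29) and Pparg (0.36) were higher in CD27_KO, but Foxp3 (−0.99), Il10 (−2.11) and Klrg1 (−0.67) were lower and Il4 (1.88) higher there, so a different mix of Treg and Th2 cells within that cluster is not excluded.

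Some genes of type 1 immunity were higher in the Treg-like cells of CD27_KO. Of 9 measured type 1 effector genes, 5 were at least 1.5-fold higher and 2 at least 1.5-fold lower, Gzmb among them (−1.12). The median was 1.52 (percentile 100), with Ccl4 at 3.40, Cxcr3 at 2.24 (1.84 to 2.66), Ccl5 at 2.16 (2.03 to 2.30) and Ifng at 1.65. It was 0.22 over members with at least 100 UMIs and −0.02 over all cells with a Foxp3 UMI, so it rests on sparse members and on this class; Tbx21 had 8 and 12 UMIs. The interferon-induced GTPase gene Iigp1 was 14.5-fold higher (8.40 to 26.7), and interferon response genes had a median of 0.50 (percentile 99.3). Serpina3g, Slfn1 and Entpd1, which encodes the ectonucleotidase CD39, were between 3.97-fold and 5.19-fold higher. Early activation genes were lower (median −1.01, percentile 0; Ier3 −2.17, Nr4a1 −1.82, Ifrd1 −1.73, Nr4a3 −1.64), as were dissociation and immediate early genes (−0.92, percentile 0; Atf3 −4.19, Fos −1.62, Fosb −1.48, Zfp36 −1.44). TRAF and NF-kB genes had a median of −0.42 (percentile 0; Nfkbia −1.04, Rel −1.06) and the TNF receptor list of −0.35, with Tnfrsf25 at −1.91. Over all cells with a Foxp3 UMI these medians were nearer 0, at −0.32 for early activation, −0.31 for dissociation, 0.02 for TRAF and NF-kB (percentile 22.0) and −0.05 for the TNF receptor list (6.37). Cd27 had 261 UMIs in WT and none in CD27_KO Treg-like cells, 45.4-fold lower against a floor of 3 counts (lower limit 36.6). Nrn1 was 16.3-fold, Cxcl3 13.3-fold and Ly6c1 8.86-fold lower, and Cxcl2 was at −2.81. Of 3184 genes, 328 were at least 1.5-fold higher and 198 lower (205 and 250 relative to the median gene of the class; 17.6 and 29.2 from counting error).

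Th2-like cells (290 WT and 1078 CD27_KO) differed in their cytokine transcripts. Gata3 was at 0.47 (0.32 to 0.62) and Il1rl1 at 0.42 (0.29 to 0.55) on the log2 scale. Il4 was higher in CD27_KO (0.90, 0.53 to 1.29), while Il13 (−1.65, −2.05 to −1.24), Il5 (−1.46, −1.79 to −1.13), Csf2, the gene of GM-CSF (−1.35), and Areg (−0.91) were lower; the list median was −1.13 (percentile 0). A few cells carried much of the Il13 signal, since 69.9% of all WT Il13 UMIs came from 5 cells; for Il5 the share was 33.2%. The shares of Th2-like cells with a UMI went the same way after thinning, from 11.4% in WT to 3.73% in CD27_KO for Il5 (15.9% and 6.68% before), from 6.05% to 2.15% for Il13 (6.90% and 3.62%) and from 9.25% to 17.9% for Il4 (14.1% and 28.1%).

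Some type 1 transcripts were sparser in the Th2-like cells of CD27_KO (median −1.37, percentile 0). Of 6 measured members, 4 were at least 1.5-fold lower and 2 were not, Ifng among them (0.02, on 5 and 20 UMIs). Nkg7, a granule protein gene, was 5.48-fold lower (3.69 to 8.19), Ccl5 4.53-fold lower (3.84 to 5.35) and Cxcr3 2.99-fold lower (1.64 to 5.38). Txk, a T cell kinase gene, was 4.71-fold and Cxcl2 3.02-fold lower. The VAT Treg signature had a median of 0.29 (percentile 99.0), but none of its 9 measured members was 1.5-fold higher and Areg was lower; interferon response genes were at 0.32 (97.4), a value that rests on sparse members. Dissociation genes were at 0.01 (57.2). Samd11 was 11.1-fold, Tmem181a 5.03-fold, Crebl2 4.13-fold, Plac8 3.27-fold, Dach2 3.22-fold and Coro7 2.98-fold higher, on 5 to 15 WT UMIs each. Of 4152 genes, 315 were at least 1.5-fold higher and 112 lower (233 and 143 relative to the median gene of the class; 89.6 and 40.3 from counting error).

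**Figure D3:**
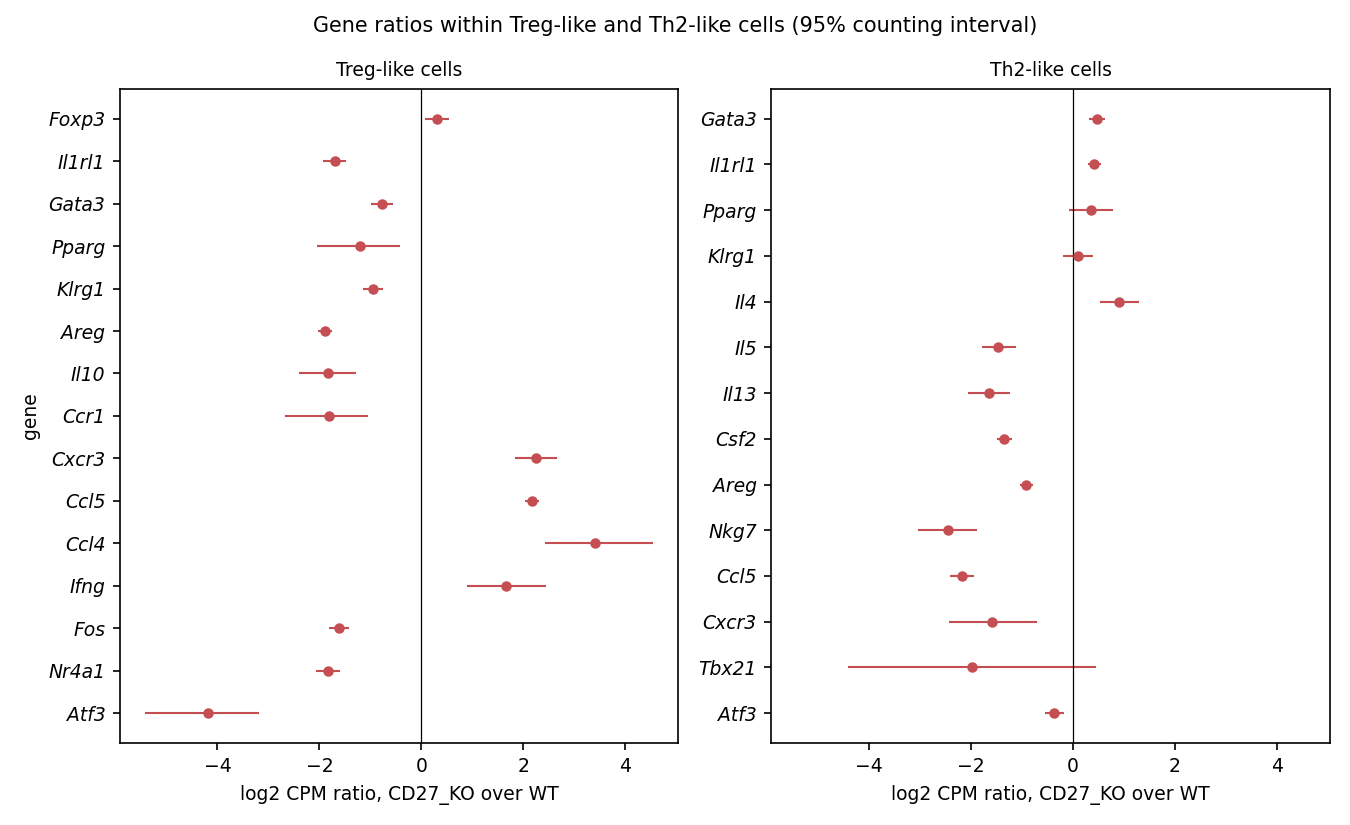
Log2 CPM ratio of CD27_KO over WT (x axis) for selected genes within Treg-like cells (left) and Th2-like cells (right), 1 library per group; lines are 95% counting intervals. Foxp3 is at 0.31 and Il1rl1 at −1.70 in Treg-like cells, and Il4 is at 0.90 and Il5 at −1.46 in Th2-like cells.

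Th1-like cells (1958 WT in clusters 0, 3, 10 and 11, and 3047 CD27_KO) leaned away from lymph node homing in CD27_KO. Recirculation genes had a median of −0.38 (percentile 0), with Ccr7 at −2.48 (−3.03 to −1.97). Residency genes were at 0.29 (percentile 99.0), with Cxcr6 at 0.86 and Bhlhe40 at 0.77. Type 1 effector genes were lower as a list (−0.29, percentile 0), and the cytotoxic gene Gzmb was 4.22-fold lower (2.86 to 6.37), yet Ifng was at 0.55 (0.41 to 0.69). Il4 was 5.76-fold higher (3.43 to 10.4) on 16 and 143 UMIs. Furin, the gene of a proprotein convertase, was 4.31-fold higher (3.68 to 5.08), and Epas1, the gene of HIF-2alpha, 3.87-fold. Samd11 was 11.2-fold, Tmem181a 4.94-fold and Dynlt1a, which has near-identical copies, 3.30-fold higher. Foxp3 was 5.40-fold and Cxcl2 5.07-fold lower, on 101 and 29 and on 85 and 26 UMIs, and Cd27 had 639 and 4 UMIs. Dissociation genes were at −0.22 (percentile 0). Of 7715 genes, 439 were at least 1.5-fold higher and 137 lower (206 and 231 relative to the median gene of the class; 25.4 and 17.1 from counting error). Since the 4 clusters take unlike shares in the 2 libraries, these values mix a difference in their proportions with any difference within them.

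Naive-like cells (1274 WT and 307 CD27_KO) were higher in recirculation genes as a list in CD27_KO, by little per gene. The median was 0.35 (percentile 99.6), but only 1 of 11 was at least 1.5-fold higher, Klf3 at 0.86, with Ccr7 at 0.55, Il7r at 0.49 and Tcf7 at 0.45. Dissociation genes were lower (−0.27, percentile 0.01), with Socs3, an inhibitor of cytokine signalling, 3.11-fold lower (1.58 to 6.99) on 109 and 9 UMIs. The cell cycle kinase gene Cdk6 was 4.54-fold lower (2.33 to 10.1) on 159 and 9 UMIs, and Ecm1 3.43-fold lower. Arfgef1, Ikbke, Trpm7, Csnk1g3 and Ppp1r21 were between 2.29-fold and 2.71-fold higher. Akr1b7 was again at 0 in WT and had 360 UMIs in CD27_KO, nearly all from few cells, and Cd27 had 322 and 3 UMIs. Of 3012 genes, 283 were at least 1.5-fold higher and 84 lower (141 and 150 relative to the median gene of the class; 31.2 and 68.9 from counting error). In this class the count of lower genes is near what counting error gives.

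Gstp1, a glutathione transferase gene, was 3.46-fold lower in the naive-like cells of CD27_KO (log2 −1.79), and was also lower in Treg-like (−1.78), Th1-like (−1.47) and Th2-like cells (−1.21). It has near-identical copies elsewhere in the genome, so the origin of its reads is uncertain.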

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

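In the weighing of the larger Th2-like and smaller Treg-like share, both tests for naive-like cells were chosen only after the result was seen, and the tests for depth and doublets took their final form then, as thinned cells gave no named Th2-like cluster and Scrublet marked no cell. Loss of naive-like cells alone would raise all other classes alike and leave the ratio of Th2-like to Treg-like cells as it was. That ratio was 8.92 times larger in CD27_KO (7.39 to 10.8), against this loss as the only cause. The value restates the 2 shares that made up the pattern, so it is no independent support. The Treg-like ratio outside the naive-like class, 0.317 (0.277 to 0.361), could only fall below 0.381 and decides nothing. Thinning all cells and clustering again left a ratio of 3.43 (3.06 to 3.86) for the cluster that held most Th2-like cells, against a cause in depth. Without top-scored doublets and high-UMI cells the Th2-like ratio was 2.63 (2.23 to 3.11), against doublets as the whole cause. The Th2-like share was then 3.73% in WT and 9.81% in CD27_KO, against 4.68% and 15.9% in the main result, so its size depends on this removal. A difference between mice, pools or sorting days stays open, since no replicate exists.

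In the weighing of the lower VAT Treg signature and immediate early genes in Treg-like cells, the test over cells with a Foxp3 UMI was chosen only after the result was seen. Stress during dissociation of 1 pool would shift the dissociation list in all 4 classes, and its median was 0.0143 in Th2-like cells, short of that. Atf3, a member of this list, was among the leading genes of the Th2-like class, so its cells were chosen partly by such a gene. The value therefore does not decide whether stress was the whole cause. The list median was lower in the other 3 classes, at −0.22 in Th1-like, −0.27 in naive-like and −0.92 in Treg-like cells, so stress as a cause stays open. Over all T cells with a Foxp3 UMI the signature median was −0.37, between the values set for a cause in clustering and for none. A loss of VAT character and a different placement of Treg cells, for example in unnamed cluster 6, cannot be told apart, because this value lies between both limits.

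In the weighing of genes apart in every class and genes near Cd27, the tests over the 139 genes at least 2-fold apart with classes given the same share were chosen only after the result was seen. Of 11 genes apart in every class, 81.8% (48.2 to 97.7) had a near-identical copy, against 21.2% of 500 other genes, so reads shared with copies may explain Gm10076 and Dynlt1a; over the larger set the share was 27.7% (20.4 to 36.0), which leaves this open. For DNA of another background in 1 pool, neighbouring pairs lay at percentile 36.1 for the 11 genes, which held 0 pairs and so had no power, and at 99.05 for the 139 genes (87 pairs, random median 58), but at 94.75 without copied genes. For strain DNA beside the mutated Cd27, the list fixed beforehand lay at percentile 8.7, short of what this cause was set to give. A median over its 24 measured genes would not move if only a few of them differed, so this value does not decide. The window around Cd27 lay at 99.61, with 6 of 72 genes apart. These 6 include Usp18, the furthest interferon response gene over all T cells. They also include natural killer receptor genes that may be regulated together, so these explanations cannot be told apart without sequence variants.

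Some sorted cells were not T cells and were not analysed here. A cluster with dendritic cell markers held 55 WT and 27 CD27_KO cells, one with B cell and macrophage markers 52 and 27, and one with stromal progenitor markers 29 and 11.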

How the results depend on the processing

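Of the alternative results, 291 stayed within their limits, 92 moved beyond them and 9 changed direction. All of these 9 except the Treg-like chemokine receptor list had stood outside the random range or counting error. The main median of that list, −0.13, lay inside its random range of −0.14 to 0.40. A further 47 list medians that had lain inside the random range changed sign, 21 of them under median-of-ratios scaling. Alternatives added after the results were seen are marked as added, and the cause of a difference was not tested.

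The Th1-like ratio of 1.42 was the least stable share. It changed direction at resolution 1.5 (0.875), with thinned cells clustered again (0.530) and with the added removal of doublets and high-UMI cells (0.852). It was 3.34 under the strict filter, 3.11 at resolution 0.6, 1.81 with WT clustered alone, 1.18 with the added choice of variable genes without Treg genes, 1.53 without clusters 3 and 6 (added), 1.18 outside the naive-like class (added) and 1.07 outside it and cluster 4 (added). The naive-like ratio was 0.315 under the strict filter, 0.339 with every barcode, 0.297 at resolution 1.5, 0.321 without Th2 and type 2 genes, 0.337 with WT clustered alone, 0.354 with thinned cells and 0.395 with doublets removed (added), so the main value of 0.220 is a low one.

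The Treg-like ratio stayed below 1 and the Th2-like ratio above 1 throughout. The Treg-like ratio was 0.255 under the strict filter, 0.330 without Th2 and type 2 genes, 0.298 without Treg genes (added), 0.145 with WT clustered alone, 0.317 outside the naive-like class (added) and 0.286 outside it and cluster 4 (added). The Th2-like ratio was 3.93 at resolution 0.6, 2.92 with WT clustered alone, 2.63 with doublets removed (added), 2.83 outside the naive-like class (added) and 2.55 outside it and cluster 4 (added). Clustering of thinned cells named no Th2-like cluster, and the settings outside the naive-like class have no naive-like share.

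Counts of genes followed the limit and the scaling. Over all T cells they were 1117 higher and 566 lower at 30 UMIs, 381 and 147 at 300 UMIs, 409 and 178 with classes given the same share, and 324 higher with median-of-ratios scaling. At 30 UMIs they were 1069 and 408 in Th2-like, 1106 and 491 in Treg-like, 1005 and 440 in naive-like and 854 and 331 in Th1-like cells. Median-of-ratios scaling gave 205 higher in Treg-like, 141 and 150 in naive-like and 206 and 231 in Th1-like cells. Thinning gave 151 and 70 in Th2-like and 152 and 129 in Treg-like cells, 181 higher in naive-like and 87 lower in Th1-like cells.

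Among the lists, median-of-ratios scaling gave 0.15 for tissue residency, −0.56 for recirculation, 0.26 for interferon response and 0.56 for cell cycle, and changed the direction of the list near Cd27 (−0.12). Classes given the same share gave −0.80 for type 2 cytokines, whose main median of 0.19 had the other sign, 0.13 for residency, −0.0485 for recirculation and 0.24 for cell cycle, and changed the direction of costimulation (0.061). With members of at least 100 UMIs, the Treg-like type 1 effector median was 0.22. Under that limit glycolysis (0.0465) and chemokine receptors (0.15) changed direction in Treg-like cells. So did the list near Cd27 in Th1-like cells (0.0052). The main Treg-like median of chemokine receptors, −0.13, had lain inside its random range. With doublets removed (added), the Treg-like type 1 effector median was 0.64 and Treg-like glycolysis changed direction, to 0.0024. At 2600 UMIs the ratio of shares with a Gata3 UMI was 1.30 and that with an Il5 UMI 1.93, a setting that changes the depth and also leaves out 4398 WT and 4251 CD27_KO cells.

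No paired analysis was possible because both libraries are replicate 1 and each group has 1 library.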

Other observations

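The NK-receptor-like class had fewer Klrb1c and Klrb1f transcripts in CD27_KO while Klrd1 and Klrk1 did not, and these genes were chosen after their values were seen. In that class Klrb1c had 85 WT and 10 CD27_KO UMIs (log2 −2.28, −3.39 to −1.33) and Klrb1f was at −1.45 (−2.07 to −0.87). Klrc2 was at −0.96 (−1.76 to −0.22) and Clec2i at −0.59 (−1.52 to 0.28), against 0.41 for Klrd1 and 0.13 for Klrk1. Klrd1, Klrk1, Klrb1f and Klrc2 were among the leading genes of this class, so its cells were chosen partly by them. The values of Klrd1 and Klrk1 therefore do not decide whether these genes were spared. The class held 111 CD27_KO cells, fewer than the limit set for counting genes apart within a class. Klrc2 has near-identical copies, so the origin of its reads is uncertain. The contrast with Klrb1c was absent from Th1-like cells, where Klrd1 and Klrk1 were both lower, at −2.03, as was Klrb1c, at −1.91. All 6 genes lie near Cd27 on chromosome 6. The antisense model Gm15987 in the same region had 2 WT and 663 CD27_KO UMIs, spread over 565 CD27_KO cells.

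The share of T cells with an Il5 UMI after thinning to 1300 UMIs had a ratio of 1.08 (0.722 to 1.62) although the Th2-like share was 3.40 times larger in CD27_KO; the fraction of Th2-like cells with Il5 was lower there, at 3.73% against 11.4%. The ratio was 1.62 (1.22 to 2.16) without thinning and 1.93 among the deeper cells used at 2600 UMIs, so the value near 1 could depend on the depth or on the cells used. Il4 went the other way, with a ratio of 5.496 (4.20 to 7.30), and was also among the leading genes of unnamed cluster 8.

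A second pool per group would show which shares differ between mice. Reads spanning Cd27 and sequence variants on chromosomes 4 and 6 would separate strain DNA from regulation for Samd11, Mxra8, Tnfrsf14 and the natural killer receptor genes. Staining for Foxp3, ST2 and intracellular IL-4, IL-5 and IL-13 would test the cytokine differences per cell.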
